A study of Mus musculus with 15 samples.

How the data were processed

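Total RNA from the mouse KP1 line and its resistant derivatives was extracted with Qiagen RNeasy kits and made into stranded libraries with the Roche KAPA kit, per the labels. The 15 libraries form 5 groups of 3: parental cells in DMSO, parental cells in EPZ015666, and the lines R3, R6 and R7 in DMSO. Per the submitters' processing notes, reads were aligned to mm10 with STAR 2.5.3a and quantified with RSEM 1.3.0. The annotation, the strand setting and the filters are not given in the sources used here. The deposited estimated counts are RSEM-type values per Ensembl gene, stored as whole numbers and not scaled, which the authors made with 1 column per library. The deposited log2 values are the binary logarithm of TPM (transcripts scaled to a common total per library) plus 1, made by the authors from the same quantification. Both hold 50686 genes. The TPM summed to between 999999 and 1000000 per library, 943 values had a count of 0 beside a TPM above 0, and every column matched a sample label.

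Depth ran from 6811075 to 13260719 counts per library (median 7926600). R7 replicate 3 was the deepest, and EPZ015666 replicate 2 the shallowest. Symbols came from GENCODE M21, on the same build, for 50376 identifiers (99.39%). Those without a symbol held 0.0713% to 0.0874% of the counts, and 13229 of the tested genes had mm10 coordinates. Mitochondrial genes took 0.829% to 2.498% of the counts and Gm42418, a predicted gene that overlaps ribosomal RNA, 0.185% to 2.644%. TMM factors lay between 0.957 and 1.033. No pair of libraries of 1 group was as close as counting noise alone would make duplicates (chi-squared per degree of freedom 2.97 to 20.76).

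Tests were run in R 4.3.3. Of 50686 genes, 23772 had no count in any library and 13259 passed edgeR's filterByExpr. edgeR 4.0.16 fitted all 15 libraries in 1 negative binomial model with TMM factors (common dispersion 0.0116, 10 residual degrees of freedom), and each comparison used the quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors of log2 fold changes are approximate SE worked back from that test, as the absolute log2 fold change over the square root of F. Errors of CPM are SD over libraries. Compared were EPZ015666 with DMSO in parental cells, each resistant line and their mean with DMSO-treated parental cells, the mean of the lines with EPZ015666-treated parental cells, and each pair of lines. Genes were called shared when past the threshold with the same sign in all 3 lines. Fold values against a group with 0 counts use a floor of 3 counts over the group, and those against 1 to 3 counts carry 95% counting intervals. Log2 values, those with 1 library left out included, are as fitted and do not use the floor. Where a group is left with 0 counts, their size is not set by the data. The comparisons, lists, named-gene rule and first set of alternatives were chosen before the data were examined.

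Gene groups were 39 lists with 687 symbols, of which 2 were matched by a synonym. They were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes, and again with an estimated correlation. Of these lists 36 had at least 2 measured members. The germline list (highest mean Rhox5, 0.581 CPM), the Y-linked list (Kdm5d, 0.0337 CPM) and the stromal list (Pdgfra, 0.537 CPM) had none and were not tested. The lists for leukocytes and for endothelium kept 2 members each. Placing members with 3 counts or fewer at their bound left every list median as fitted. Counts adjusted over the list alone are given where they differ from those over all genes, and are otherwise the same.

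Genes were named by a fixed rule. Stmn2, Prmt5, Kras and Trp53 were always named. For EPZ015666 the rule took the 10 highest and 10 lowest log2 fold changes past the threshold, with at least 5 CPM in the higher group and no overlap between the libraries of the groups, a condition that 10% of genes meet by chance with 3 against 3. Predicted and clone names were left out. For the lines it took the 10 rises and 10 falls whose smallest change over the 3 lines was largest, for each line 3 rises and 3 falls that also differed from both other lines, and for the lines against EPZ015666 the 5 highest and 5 lowest. From each list up to 2 rises and 2 falls with at least 1 CPM in the higher group were taken. List members whose call ended when a single library was left out were counted but mostly not named. Hnf4a was named after its values were seen.

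The first set of alternatives was DESeq2 size factors in edgeR, DESeq2 1.42.0 with its Wald test, limma with trend on the log2 TPM, no filter on low counts, a filter of at least 1 CPM in 3 libraries, only the libraries of the groups compared, the replicate number as a block, and leaving out each library in turn. Unless stated, values with 1 library left out are those for libraries of the groups compared. The fit without the filter gave very small p-values to Lars2 and Mir6236 despite their wide spread between libraries. Calls made only in that fit therefore carry little weight. Added after seeing the data were the series of library numbers as a term (37 to 51, 53 to 57, and 71 with 72, which the column labels carry), a fit of only the 9 libraries numbered 37 to 51, a fit without R6 replicate 1, DMSO replicate 3 and EPZ015666 replicate 3, and the removal of chromosome medians. Libraries numbered 53 to 57 or 71 and 72 hold at most 1 library of a group, too few for values of their own. A lone library of a group was assumed to vary like the other groups.

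The test was tried on simulated data with the dispersions of these libraries, in which 200 of the genes were changed for EPZ015666 and another 200 for the lines, each with 50 at each size. For EPZ015666 against DMSO, changes of 1.25, 1.5, 2 and 4-fold were recovered in 8%, 50%, 68% and 90% of genes, and 3 of 12366 unchanged genes were called. For R3 the shares were 10%, 48%, 76% and 86%, for the mean of the lines 26%, 56%, 82% and 92%, and for the lines against EPZ015666 34%, 60%, 84% and 96%. Camera called 10 of 10 lists shifted by 0.5 on the log2 scale and 0 of 30 unshifted ones. These lists held random genes simulated independently, so they do not test false calls for lists whose members vary together. Changes under 1.5-fold were thus often missed in this simulation. Far more genes were called in the data (27.6% for EPZ015666), which makes the adjusted threshold less strict there. The simulated shares need not hold for the data.

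Overlap between comparisons that share the DMSO libraries was set against 40 simulations without group effects. Chromosome medians used 10536 genes with a mean of at least 5 CPM, and bins of 20 Mb with at least 20 genes (137 bins). No isoform, splicing or sequence-level results were computed, because the files hold gene totals only, and no reads were used.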

Results

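RNA-seq was available for 15 libraries from a mouse lung adenocarcinoma cell line, KP393T5 (called KP1 or parental), which carries mutant Kras and is p53 null per the labels, and from 3 lines derived from it. EPZ015666 is a small-molecule inhibitor of PRMT5, an enzyme that places symmetric dimethyl marks on arginine. Parental cells were kept for 72 h in 10 µM EPZ015666 or in its solvent, 0.1% DMSO. The resistant lines R3, R6 and R7 came from cells that survived 12 days in 10 µM EPZ015666, and were harvested after 72 h in DMSO, without the inhibitor. Each of the 5 groups had 3 libraries. Total counts ran from 6811075 to 13260719 per library, with a median of 7926600, and between 16950 and 19297 genes had at least 1 count. The labels do not say whether the 3 replicates of a group were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The first principal component (58.1% of the variance) parted the resistant libraries (23.9 to 56.8) from the parental ones (-73.8 to -56.3), and R6 replicate 1 lay at 23.9, beside 51.5 and 56.8 for the other R6 libraries.

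Stmn2 encodes a microtubule-destabilizing protein of the stathmin family, known mainly from neurons, and is the gene named in the series title in connection with acquired resistance. It was low in the parental cells and high in every resistant line. Its level was 2.49 ± 1.73 CPM (counts scaled by the TMM-adjusted library total; SD, n = 3) in DMSO-treated parental cells, 7.72 ± 4.21 after EPZ015666, 197 ± 7.45 in R3, 129 ± 11.9 in R6 and 121 ± 7.46 in R7. Against DMSO-treated parental cells this was 77.4-fold higher in R3, 50.8-fold in R6 and 47.7-fold in R7, and 3.04-fold higher after 72 h of EPZ015666. The gene (ENSMUSG00000027500) lies on chromosome 3, from 8509360 to 8561606 on the plus strand of mm10.

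By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over 13259 genes, the log2 fold change of Stmn2 was 6.27 ± 0.28 (SE) in R3, 5.67 ± 0.29 in R6 and 5.58 ± 0.29 in R7, with adjusted p of 9.99e-10, 1.64e-09 and 3.36e-09. All 9 resistant libraries lay above all 6 parental ones. After EPZ015666 it was 1.60 ± 0.39 (adjusted p = 0.00673), with each treated library (4.91 to 12.6 CPM) above each control (1.46 to 4.48 CPM). These values leaned on single parental libraries. Without DMSO replicate 3 (4.48 CPM) they became 7.03 in R3, 6.43 in R6, 6.34 in R7, 6.60 in the mean of the lines and 2.35 after EPZ015666, and without EPZ015666 replicate 3 (12.6 CPM) the drug value became 1.07 (adjusted p = 0.0297 for the latter). The 9 libraries numbered 37 to 51 gave 1.82 after EPZ015666 and 6.59 for the mean of the lines, against 5.84 over all libraries. The resistant lines also exceeded EPZ015666-treated parental cells, by 4.24 ± 0.23 (18.8-fold, adjusted p = 8.04e-10).

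**Figure D1:**
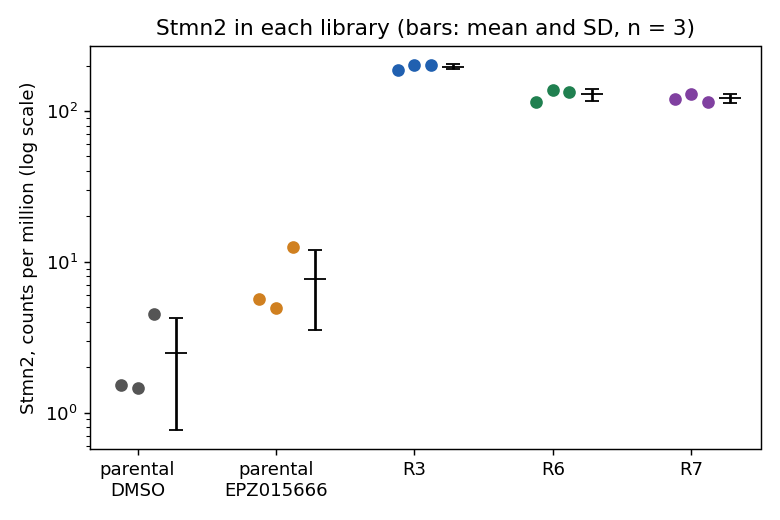
Stmn2 in CPM on a log axis, 1 point per library, with the mean and SD of each group of 3. The 9 resistant libraries sit above all 6 parental libraries, and the EPZ015666-treated parental libraries sit between.

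Prmt5, which encodes the target of the inhibitor (ENSMUSG00000023110, chromosome 14, 54507187 to 54517525, minus strand), was nearly level across groups. It measured 101 ± 4.73 CPM in DMSO and 115 ± 7.06 after EPZ015666 (log2 fold change 0.20, adjusted p = 0.0391 by the edgeR quasi-likelihood test). That call was lost without DMSO replicate 1 (adjusted p = 0.0745), DMSO replicate 2 (0.176), DMSO replicate 3 (0.0639), EPZ015666 replicate 1 (0.168) or EPZ015666 replicate 3 (0.107), and with limma on log2 TPM (0.158). In R3 the value was 0.19 (adjusted p = 0.0297), lost without DMSO replicate 1 (0.0541), DMSO replicate 2 (0.119), R3 replicate 1 (0.0902) or R3 replicate 2 (0.051). In R6 it was 0.07 (adjusted p = 0.431) and in R7 0.13 (adjusted p = 0.139). Kras, the mutated oncogene of the line (ENSMUSG00000030265, chromosome 6, 145216699 to 145250239, minus strand), was at 142.1 ± 6.45 CPM in DMSO and at 142.5 ± 15.9 after EPZ015666, and the mean of the lines differed by -0.04 (adjusted p = 0.713). Trp53, which encodes p53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873, plus strand), gave RNA counts in every group although the line is labelled p53 null. It rose from 3.81 ± 0.189 to 7.85 ± 1.43 CPM after EPZ015666 (1.04, adjusted p = 0.000805), to 8.21 CPM in R3, and by 0.66 in R6 and 0.87 in R7 on the log2 scale. In R6 the Trp53 call ended once the median shift of each chromosome was removed (0.37, adjusted p = 0.116).

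In parental cells, 72 h of EPZ015666 was set against DMSO to ask what the inhibitor does before resistance arises. Among the rises, Krt14, a keratin of basal epithelial cells, went from 0.527 ± 0.217 to 9.45 ± 2.95 CPM, Sbsn, the epidermal protein suprabasin, from 0.829 ± 0.509 to 5.54 ± 0.313, and Sprr2h, a small proline-rich protein of the cornified envelope, from 7.58 ± 0.929 to 30.2 ± 4.40. Csf2, the cytokine GM-CSF, rose from 1.06 ± 0.118 to 5.74 ± 1.43 CPM and Thbd, the thrombin receptor thrombomodulin, from 2.90 ± 0.952 to 12.0 ± 1.06. Among the falls, Csad, an enzyme of taurine synthesis, went from 10.9 ± 2.23 to 1.66 ± 0.261 CPM, Ldhd, a D-lactate dehydrogenase, from 15.8 ± 1.61 to 2.68 ± 0.253, and Dhrs4, a carbonyl reductase, from 18.4 ± 0.451 to 4.29 ± 0.884.

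On the log2 scale the rises were 4.12 ± 0.59 for Krt14 (adjusted p = 0.00028 by the edgeR quasi-likelihood test), 2.70 for Sbsn, 2.42 for Rab26os, an antisense transcript (counted on a strand setting that the sources do not give), 2.41 for Csf2, 2.05 for Bcl2l15, 2.03 for Thbd, 1.99 for Sprr2h and 1.96 for Rasgrf2, a RAS exchange factor. Their adjusted p ran from 5.72e-06 for Rab26os to 0.000913 for Rasgrf2. Lars2, the mitochondrial leucyl-tRNA synthetase (2.17), and the microRNA gene Mir6236 (2.27) also passed, but with a wide spread: Lars2 was at 2449 ± 1886 CPM against 546 ± 91.0. Gm42418, a predicted gene that overlaps ribosomal RNA, took 0.317%, 2.444% and 2.644% of the counts in the treated libraries and 0.311% to 0.958% in the controls. Both calls were lost without EPZ015666 replicate 3 (1.33 for Lars2 with adjusted p = 0.129, and adjusted p = 0.22 for Mir6236) and without DMSO replicate 1 (0.055 and 0.073), 2 (0.0865 and 0.115) or 3 (0.0644 and 0.095), and in the 9 libraries numbered 37 to 51 (0.0613 and 0.111). The falls were -2.71 ± 0.20 for Csad (adjusted p = 6.33e-07), -2.63 for the sterol reductase Tm7sf2, -2.56 for Ldhd, -2.55 for Fam173a, -2.54 for Amdhd2, which removes the acetyl group of N-acetylglucosamine 6-phosphate, -2.30 for Pklr, the pyruvate kinase of liver and red cells, -2.12 for Ift43 of ciliary transport, -2.09 for Dhrs4, -2.06 for Gpr108 and -2.03 for Pgghg.

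EPZ015666 changed 3663 of 13259 genes, 1714 higher and 1949 lower, of which 314 rose and 286 fell at least 2-fold. The 9 libraries numbered 37 to 51 gave 4044 genes (1838 higher, 2206 lower). Without the 3 libraries that stand apart from their groups (R6 replicate 1, DMSO replicate 3 and EPZ015666 replicate 3) the count was 2776 (1188 higher, 1588 lower). With limma on log2 TPM the share of higher genes was 32.5% (936 higher, 1945 lower) against 46.8%.

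**Figure D2:**
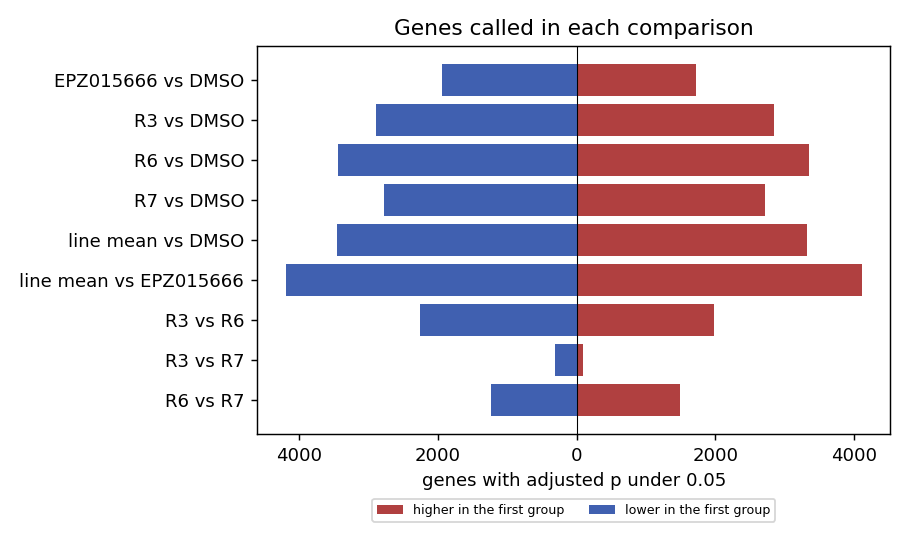
Number of genes past the adjusted p threshold in each comparison, drawn to the right of 0 for genes higher in the first group and to the left for lower ones. Counts run from 416 genes between R3 and R7 to 8306 between the resistant lines and EPZ015666-treated parental cells.

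Stress genes under ATF4, the transcription factor of the integrated stress response, rose with EPZ015666. Of 17 measured members 15 rose and none fell, and 16 rose when adjusted over the list alone. Ddit3, the stress transcription factor CHOP, went from 5.22 ± 0.370 to 19.4 ± 0.622 CPM (log2 fold change 1.89, adjusted p = 1.89e-05), and Trib3, a pseudokinase that restrains ATF4 signalling, from 11.2 ± 1.65 to 40.7 ± 3.02 (1.86, adjusted p = 4.3e-06). Cholesterol synthesis genes fell: 14 of 20 fell and none rose (16 adjusted over the list alone), with Nsdhl, a sterol dehydrogenase, from 92.8 ± 5.92 to 42.9 ± 6.77 CPM (-1.11). Among 17 targets of NRF2, the oxidative stress factor, 2 rose and 11 fell (12 fell adjusted over the list alone). Hmox1, heme oxygenase, rose by 1.01 and the cystine transporter Slc7a11 by 0.63, while the glutathione transferase Gstm1 fell from 112.5 ± 13.4 to 43.3 ± 13.8 CPM (-1.38). Of 9 measured neuronal and neuroendocrine genes other than Stmn2, 7 rose and none fell (8 adjusted over the list alone), all from low levels.

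The neuronal gene Gap43, a growth cone protein, stood at 2.51 ± 0.558 CPM against 0.355 ± 0.383 (2.77, adjusted p = 0.0127 by edgeR), a call lost without DMSO replicate 1 (0.0604) or 3 (0.0672), in the 9 libraries numbered 37 to 51 (0.0559) or without the 3 libraries that stand apart (0.0975), with a value of 4.08 without DMSO replicate 2. Prph, the neuronal filament peripherin, was at 4.41 ± 0.126 against 1.45 ± 0.681 (1.59, adjusted p = 0.0103), lost without DMSO replicate 1 (0.057) or 2 (0.0502). Of 19 p53 targets 8 rose and 2 fell (9 and 2 adjusted over the list alone). The line is p53 null per the labels and p53 activity was not measured, so the name of the list says nothing on it. Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose by 1.19 and Sesn2, which also sits in the ATF4 list, by 1.13, while the antiproliferative gene Btg2 fell by 0.90 and Sesn1 by 0.50. Of 20 nucleolar and ribosome biogenesis genes 7 rose and 2 fell (10 and 2 adjusted over the list alone), with Mybbp1a at 1129 ± 87.0 against 816.7 ± 46.9 CPM (0.47) and Rrp12 rising by 0.61.

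These 6 lists passed camera with its preset correlation, with adjusted p of 4.59e-17 (ATF4), 6.24e-06 (cholesterol), 0.00209 (NRF2), 0.00397 (neuronal), 0.0242 (p53) and 0.0263 (nucleolar). None passed with an estimated correlation, where limma's camera gave adjusted p = 0.098 for ATF4 and neuronal genes, 0.38 for p53 targets, 0.55 for cholesterol and NRF2 genes and 0.71 for nucleolar genes, all with an estimated correlation. Their median log2 fold changes were 0.63, -0.38, -0.41, 1.11, 0.27 and 0.21 in the same order.

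Several groups close to the inhibitor's target or to Stmn2 did not pass as groups after EPZ015666. Of 22 stathmin family and microtubule regulator genes, Stmn2 included, 6 rose and 2 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.153), with the microtubule stabilizer Map6 up by 0.94. Of 13 tubulins 3 rose and 1 fell (adjusted p = 0.195), and Tubb3, the neuronal beta-tubulin, went from 8.77 ± 1.21 to 30.3 ± 2.55 CPM (1.79, adjusted p = 3.29e-07). Of 17 arginine methyltransferase and methylosome genes 3 rose and 1 fell (0.657), with the PRMT5 cofactor Clns1a up by 0.36 and Prmt9 down (-0.45). Of 20 Sm protein and snRNP assembly genes 3 rose and none fell (2 adjusted over the list alone; 0.15), with Ddx20 of the SMN complex up by 0.54, and of 23 SR protein, hnRNP and splicing kinase genes 3 rose and 2 fell (2 and 2 adjusted over the list alone; 0.545). Of 27 G1/S and DNA replication genes 3 rose and 2 fell (0.398), of 24 G2/M and mitosis genes 5 rose and 5 fell (0.74), and of 20 DNA repair genes 3 rose and 8 fell (3 and 9 adjusted over the list alone; 0.0714), with the checkpoint kinase Atr among the falls (adjusted p = 5.05e-06). Of 8 CDK inhibitors 1 rose and 2 fell (0.657; median -0.09, mean 0.08), and of 13 BCL2 family genes 4 rose and 3 fell (5 and 3 adjusted over the list alone; 0.337), with the proapoptotic Pmaip1 up by 0.91 and Bmf at -1.62.

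The resistant lines were set against DMSO-treated parental cells to ask what they share when the drug is absent. Among the rises common to all 3, Sox11, a transcription factor of neural and progenitor cells, went from 1.46 ± 0.0575 CPM to 73.2 ± 19.4 over the 9 resistant libraries, and the transcription factor Sall3 from 0.220 ± 0.0709 to 21.4 ± 3.31. Wnt10a, a Wnt ligand, went from 1.23 ± 0.487 to 42.8 ± 8.97 CPM. Among the falls, Krt20, a keratin of gastrointestinal epithelium, was at 62.6 ± 6.82 CPM in parental cells and was 745-fold lower in R3 (95% counting interval 206 to 6160) and 935-fold lower in R7 (258 to 7730), while R6 held 3.18 ± 5.32 CPM, nearly all in replicate 1 (9.32, beside 0.12 and 0.10). Apoc2, a cofactor of lipoprotein lipase, fell from 54.4 ± 7.70 CPM, 432-fold in R3 (147 to 2100) and 542-fold in R7 (185 to 2630). Hnf1a, a hepatocyte nuclear factor, was at 12.3 CPM in parental cells, at least 97.4-fold lower in R3 and 367-fold lower in R7 (65.3 to 14500).

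For the mean of the 3 lines the edgeR quasi-likelihood test gave log2 fold changes of 5.60 ± 0.21 for Sox11 (adjusted p = 8.82e-11), 6.49 for Sall3, 5.44 for the transcription factor Sox7, 5.08 for Wnt10a, 5.13 for Mtus2 and 5.11 for Scube3. Blk, a Src-family kinase, and Fgf10, a growth factor, had 0 counts in the 3 DMSO libraries and were at least 60.2-fold and 53.7-fold higher in the lines, against a floor of 3 counts over the group, and Ptchd4, with 1 count, was 177-fold higher (31.7 to 7020). Such intervals and floors cover counting error only. The p-values for the mean hold for these 3 lines as fixed groups and leave out variation between lines. The falls were -6.53 ± 0.29 for the phosphodiesterase Pde3b (adjusted p = 3.39e-10), -5.07 for Rnf130, -5.11 for the cholesterol exporter Abcg1, -5.92 for Cyp3a13, -5.77 for Klhl13 and -7.37 for Apoc2. Clic6 was 313-fold lower in R3 (55.8 to 12400) and 393-fold in R7 (70.1 to 15600), and Anks4b 127-fold (43 to 617) and 477-fold (85 to 18900). Without R6 replicate 1 the mean over the lines moved to -9.29 for Krt20, -9.12 for Hnf1a, -8.57 for Clic6, -8.13 for Apoc2, -7.68 for Anks4b and -6.40 for Klhl13. Without R3 replicate 2 it was -7.86 for Clic6 and -7.17 for Pde3b, and without DMSO replicate 3 it was 8.96 for Ptchd4. These fits left Clic6 and Pde3b at 0 counts in R3 and Ptchd4 at 0 in DMSO. Leaving out R6 replicate 1 left Clic6 and Hnf1a at 0 in R6. Log2 values over 0 counts are fitted, and the data do not set their size. On the log2 TPM scale, where 1 is added before the logarithm, limma gave smaller values for genes near 0 in a group, such as 3.58 for Sox11. Of these named genes only Stmn2, Fgf10 (adjusted p = 0.0179), Apoc2 (-1.60) and Cyp3a13 (-1.22) also passed, each in the same direction, after EPZ015666. The Fgf10 call was lost without any 1 of the DMSO libraries (0.0502, 0.0583 and 0.0592), without EPZ015666 replicate 2 (0.0779) and with limma (0.509), that of Cyp3a13 without DMSO replicate 1 (0.0653) or 2 (0.113) or EPZ015666 replicate 1 (0.0678) or 3 (0.0753), and that of Apoc2 with DESeq2 (0.226) and limma (0.0723). Sox11 (0.14, adjusted p = 0.842) is an example of the rest, and Krt20 (-0.37, adjusted p = 0.592) passed only without the filter on low counts (0.0239) or with only the libraries compared (0.0162). With the latter Abcg1 (0.0169) and Anks4b (0.00679) passed too, Anks4b also without the filter (0.0294) and with limma (0.0413). The fit without the filter also gave very small p-values to genes of wide spread, so its calls carry little weight alone.

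R3 differed from DMSO-treated parental cells in 5732 genes (2844 higher, 2888 lower), R6 in 6790 (3352 and 3438) and R7 in 5494 (2719 and 2775). The 9 libraries numbered 37 to 51, with only 1 R3 library, gave 4583, 6573 and 5468. With limma on log2 TPM the share of higher genes in R3 was 39.2% (1862 higher, 2890 lower) against 49.6%. The direction was shared by all 3 lines for 3651 genes, 1762 higher and 1889 lower, where independent calls would give 147.4 and 156.7. In 1225 of them each line differed at least 2-fold (460 higher, 765 lower). Because the lines share the 3 DMSO libraries some overlap arises from those alone. In 40 simulations without line effects, edgeR called no gene in all 3 lines, but with at most 1 call in R3 they cannot show how much overlap the shared libraries give. The simulated correlation across genes between lines was 0.501 to 0.518 on average, against 0.810 (R3 and R6), 0.890 (R3 and R7) and 0.838 (R6 and R7) in the data. These cannot be compared directly, since real effects add to the spread in the data but not in the simulations. The covariances were 1.23, 1.35 and 1.16 in the same order, against 0.0675, 0.0696 and 0.0672 simulated on average. Genes are not independent replicates, so these correlations carry no p.

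Among the lists, epithelial genes fell most clearly in the lines: 17 of 18 fell and 1 rose. Cldn7, a tight junction protein, had 0 counts in R3 and R6 (at least 13.4-fold and 14.5-fold lower) and Esrp1, an epithelial splicing factor, had 0 counts in R3 and R7 (at least 16.5-fold and 20.7-fold lower), while the simple epithelial keratin Krt7 rose from 38.3 ± 8.33 to 232 CPM (adjusted p = 3.53e-09). Cholesterol synthesis genes fell in 18 of 20 with none rising, as Mvd did, from 59.9 ± 1.33 to 29.0 CPM (-1.05), and Pcsk9, which lowers the LDL receptor (-5.44, and -6.08 without R3 replicate 1). Of 11 ABC drug transporters 7 fell and none rose. Abcb1a, a P-glycoprotein gene, fell from 40.9 ± 4.47 to 11.3 CPM (-2.13). Of 7 MHC class I antigen presentation genes 6 rose and none fell, with the peptide loading protein Tapbp from 55.9 ± 2.02 to 138 CPM (1.29) and B2m, the light chain of class I molecules, from 75.3 ± 1.40 to 151 CPM (0.98). Tapbp lies on chromosome 17, whose genes had a median of 0.345, and B2m on chromosome 2 (-0.061). The ATF4 list, which rose in treated parental cells, had 3 rises and 9 falls of 17 in the lines, with Trib3 at -1.64, Mthfd2 of mitochondrial folate metabolism at -1.13 and Vldlr at 0.52.

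Gastrointestinal lineage genes moved both ways: 4 of 10 rose and 6 fell, with a median of -3.63. Hnf4a, a hepatocyte nuclear factor, fell from 276 ± 23.5 CPM to 9.17 in R3, 28.9 ± 26.5 in R6 and 9.51 in R7 (-4.37 for the mean of the lines). Anxa10, an annexin of gastric epithelium, moved by -6.43 (-7.53 without R6 replicate 1). Cdx2, an intestinal transcription factor, rose from 17.1 ± 2.73 to 56.6 CPM (1.68). Pdx1 of pancreas and duodenum, with 2 counts in DMSO, was 36.4-fold higher (9.98 to 302). Its fitted log2 value, 4.84, became 7.63 without DMSO replicate 3, so the data hardly set its size. Of 13 interferon-stimulated genes 7 rose and 1 fell, with the guanylate-binding proteins Gbp2 at 4.56 (5.37 without DMSO replicate 1) and Gbp3 at 2.83. Of 20 nucleolar genes 12 fell and none rose, among them Odc1, the first enzyme of polyamine synthesis, from 472 ± 33.2 to 226 CPM (-1.08) and nucleolin, Ncl (-0.61). Of 17 NRF2 targets 1 rose, the glutathione transferase Gsta2 (3.86, and 5.03 without DMSO replicate 1), and 10 fell, among them Cbr3 (-2.03) and Nqo1 (-1.42).

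By camera with its preset correlation these 9 lists had adjusted p of 1.26e-08 (epithelial), 1.28e-06 (cholesterol), 0.000187 (ABC transporters), 0.00285 (MHC class I), 0.00662 (ATF4), 0.0159 (gastrointestinal), 0.0159 (interferon-stimulated), 0.0403 (nucleolar) and 0.0403 (NRF2). None passed with an estimated correlation by limma's camera: adjusted p = 0.17 for epithelial, ABC and MHC class I genes, 0.48 for gastrointestinal, 0.49 for interferon-stimulated, 0.57 for cholesterol, 0.73 for ATF4 and NRF2, and 0.87 for nucleolar genes, each with an estimated correlation. The counts adjusted over the list alone were the same for all 9. Without the 3 libraries that stand apart, interferon-stimulated genes (0.0726) and NRF2 targets (0.0936) no longer passed, stathmin family and microtubule regulators did (0.032, against 0.286), and the series of library numbers as a term gave 0.0501 for gastrointestinal genes and 0.067 for NRF2 targets.

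**Figure D3:**
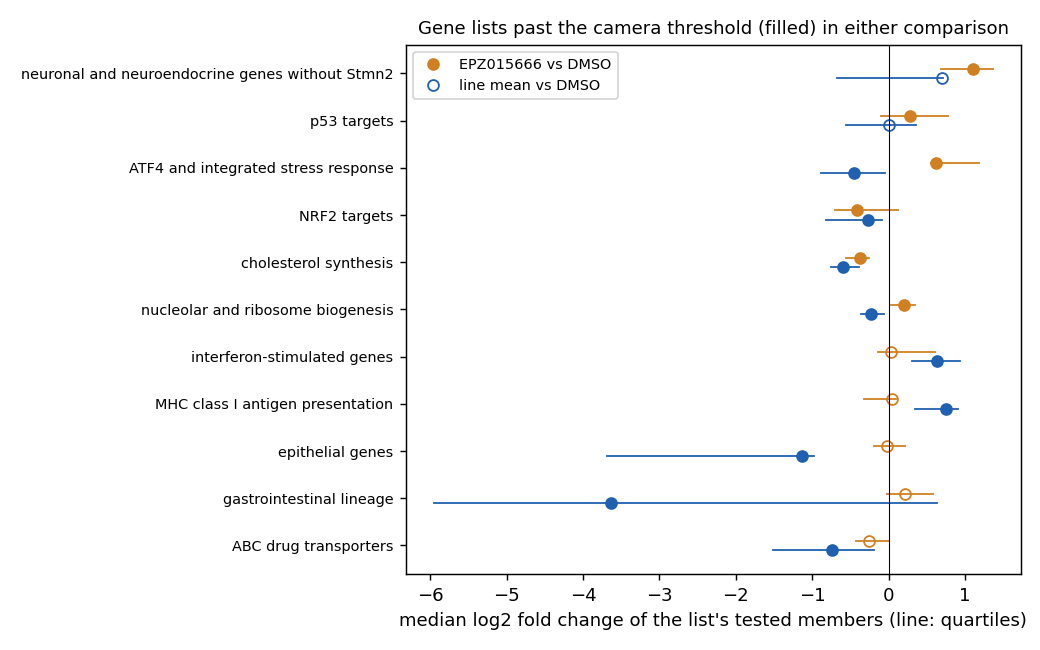
Median log2 fold change of each gene list past the camera threshold in either comparison, with the quartiles of its members as lines, for EPZ015666 against DMSO and for the mean of the resistant lines against DMSO. Filled points passed with the preset correlation, and the ATF4 list sits at 0.63 after EPZ015666 and at -0.45 in the lines.

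Within single lines, R3 carried 13 called lists, R6 had 8 and R7 had 7. Epithelial genes fell in each (16 of 18 in R3, 13 in R6, 15 in R7, with 1 rise each; camera adjusted p of 1.99e-08, 1.61e-05 and 4.64e-07, but 0.2, 0.31 and 0.23 with an estimated correlation), as did cholesterol genes (17, 15 and 15 of 20) and ABC transporters (7, 8 and 7 of 11, with 1 rise in R6), which did not pass with it either. Adjusted over the list alone, 19 cholesterol genes fell in R3, 2 ABC transporters rose in R6 and 16 epithelial genes fell in R7. G1/S genes rose in R3 (17 of 27 up, 1 down, 0.00421) and fell in R6 (1 up, 17 down, or 18 adjusted over the list alone, 0.0129). In R3 the DNA repair (11 up, or 12 adjusted over the list alone, none down), stathmin and microtubule (9 up, Stmn2 included, 3 down), tubulin (7 up, none down) and G2/M lists (10 up, 2 down) also passed, with adjusted p of 0.00551, 0.0208, 0.0459 and 0.0422, hypoxia and glycolysis genes fell in 11 of 16 (0.00925) and YAP/TAZ targets had 3 rises and 6 falls (0.0253). Of these, tubulins no longer passed with the replicate block (0.0506), with the series of library numbers as a term (0.0911) or without the 3 libraries that stand apart (0.135). G2/M genes no longer passed with the series term (0.0622) or without the 3 libraries (0.0729), nor did YAP/TAZ targets without the 3 libraries (0.135). In R6, nucleolar genes fell in 18 of 20 (1.22e-05) and interferon-stimulated genes rose in 8 of 13 (0.000382). Further calls were ATF4 genes in each line (11, 10 and 10 of 17 down, with 4 up in R6, and 1 up and 12 down in R3 when adjusted over the list alone), MHC class I genes in R3 and R7 (4 of 7 up in each), gastrointestinal genes in R3 (3 up, 6 down), and NRF2 targets (1 up and 11 down of 17) and interferon-stimulated genes (7 of 13 up) in R7. Without the 3 libraries MHC class I genes in R3 (0.135) and interferon-stimulated genes in R7 (0.0725) no longer passed. Lists that passed only then were gastrointestinal genes in R6 (0.000302, against 0.446) and R7 (1.84e-08, against 0.0711) and collagens in R6 (0.0427). With the series term splicing factors passed in R3 (0.0353) and nucleolar genes in R7 (0.00603), and in either fit ribosomal proteins in R6 (0.0462 and 0.0305) and the stathmin list in R7 (0.00603 and 0.00762). MHC class I genes in R6 (6 of 7 up, 3.51e-05) were the only list call in any comparison to hold with an estimated correlation (adjusted p = 0.034 with an estimated correlation). For the others in the single lines limma's camera gave adjusted p from 0.2 to 0.9 with an estimated correlation.

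Genes called in 1 line that also differed from both other lines were most numerous in R6 (881 higher, 649 lower), against 44 and 146 in R3 and 34 and 8 in R7. R3 held the calcium channel gene Cacna1g at 43.3 ± 1.74 CPM against 3.47 in parental cells, 14.9 in R6 and 25.4 in R7, and Col6a2, a collagen chain, at 33.9 ± 4.78 against 8.37, while Sgsm1 (-7.45, and -8.71 without R3 replicate 2), Chn2 (-6.87) and Lrig3 (215-fold lower, 59.1 to 1780) were lowest there. R6 held Gjb2, the gap junction protein connexin 26, at 31.7 ± 2.48 CPM against 1.26 in parental cells (4.65), and the collagen gene Col5a2 at 9.72 against 0.579 (4.04), and had less Map3k9 (4.62 against 18.6 CPM, -2.06), Sema5a (-3.26) and Brsk1 (-1.65). In R7, Tbx20, a cardiac T-box transcription factor, was at 11.9 ± 2.37 CPM with 0 counts in DMSO (at least 92.9-fold higher) and 1 count each in R3 and R6. Xlr was 122-fold higher (33.5 to 1010) and Pcsk5 138-fold (24.5 to 5490), and R7 had the lowest Renbp (-4.97, -5.67 without R7 replicate 2 and -4.37 without R7 replicate 3) and Fgf1 (-2.19). Without DMSO replicate 3, the only DMSO library with counts of Xlr or Pcsk5, the fitted log2 values were 9.56 for Xlr and 8.69 for Pcsk5. The data do not set the size of either. For the R6 gene Fmo2, 3.82, the value was 4.54 without DMSO replicate 2. Gfra1 (2.82 in R3) and Nrcam (-1.32 in R7) completed the genes taken by the rule.

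The lines were also compared with each other. R3 and R6 differed in 4247 genes (1985 higher in R3, 2262 lower), R6 and R7 in 2717 (1486 and 1231), and R3 and R7 in 416 (98 and 318). The 9 libraries numbered 37 to 51 gave 3063, 2052 and 234. The R3 and R7 count fell to 159 without R3 replicate 1, 255 without R3 replicate 3, 233 without R7 replicate 1 and 221 without R7 replicate 2, and reached 929 without the filter on low counts and 1328 with the series of library numbers as a term (491 higher, 837 lower). The R6 and R7 count was 1711 without R7 replicate 3 and 1688 with limma on log2 TPM. The share of higher genes moved with limma to 32.7% for R3 against R6 (1018 and 2096, main share 46.7%) and to 6% for R3 against R7 (19 and 300, main share 23.6%). Stmn2 was higher in R3 than in R6 by 0.61 ± 0.18 (adjusted p = 0.0188 by edgeR), a call lost without R3 replicate 3 (0.0506), without R6 replicate 1 (0.0636), with DESeq2 (0.178) and with limma (0.211), its alternatives running from 4.47e-09 to 0.211. R3 against R7 gave 0.70 (adjusted p = 0.0505, alternatives from 9.39e-12 to 0.324), and R6 against R7 0.09 (adjusted p = 0.771, alternatives from 0.132 to 0.951). Over the lines 186 genes were called in opposite directions against DMSO in at least 1 pair.

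The overlap of the drug response with the lines' shared difference asks whether resistant cells, in DMSO, keep the state that the drug induces. Of the genes named for EPZ015666, Sbsn (1.51 in the mean of the lines) and Csf2 (0.95) were higher in the lines too, and Tm7sf2 (-0.62), Ldhd (-0.80) and Pklr (-6.21) lower too, Pklr by 628-fold in R7 (112 to 24800). Without R6 replicate 1 the value of Pklr was -7.26. The Csf2 call was lost in the 9 libraries numbered 37 to 51 (adjusted p = 0.0543) and with chromosome medians removed (0.058). Others stood the opposite way: Krt14 (-2.99, and -3.63 without R3 replicate 1, with the call lost in the 9 libraries at adjusted p = 0.0538), Sprr2h (-2.60) and Bcl2l15 (-1.34) were lower in the lines, and Amdhd2 (1.80, 22.8 ± 3.89 against 6.47 CPM), Gpr108 (0.70), Ift43 (0.50), Csad (0.42, lost without DMSO replicate 1 at 0.27, adjusted p = 0.097) and Dhrs4 (0.41) higher. The Krt14 mean rests on R7, with 0 counts (at least 5.3-fold lower), and on R3, with 1 count. R6 held Krt14 at 0.717, 0.4735 and 0 CPM, beside 0.277, 0.6644 and 0.6403 in DMSO. Rasgrf2 (-0.85, adjusted p = 0.0437) and Rab26os (-0.54, adjusted p = 0.046) barely passed. Rasgrf2 was lower in R3 (-1.44) and R6 (-1.42), but not in R7, at 1.359, 1.674 and 1.715 CPM beside 1.385, 1.063 and 1.409 in DMSO. Leaving out any DMSO or resistant library but R6 replicate 1 ended the Rasgrf2 call (0.0506 to 0.143), as leaving out DMSO replicate 1 or 3, R3 replicate 2 or 3, R6 replicate 3 or any R7 library did for Rab26os (0.0555 to 0.19). Thbd (0.45, adjusted p = 0.138, but 0.0183 in the 9 libraries), Pgghg (0.20, adjusted p = 0.196), Fam173a (0.03, adjusted p = 0.899), Lars2 (0.88, adjusted p = 0.191) and Mir6236 (0.91, adjusted p = 0.262) did not pass edgeR in the mean of the lines, although Lars2 (5.22e-33) and Mir6236 (2.45e-25) did without the filter on low counts. The p-values without the filter do not reflect the spread between libraries. Lars2 ran from 333 to 2566 CPM over the resistant libraries, beside 443.4 to 617.9 in DMSO. Mir6236 ran from 20.68 to 201.6 CPM, beside 27.9 to 42.52. In R3 alone Thbd passed (0.82, adjusted p = 0.0306), a call lost without DMSO replicate 1 (0.13), DMSO replicate 2 (0.0704) or R3 replicate 1 (0.162).

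In all, 570 of the 3651 shared genes were called in the same direction after EPZ015666 and 555 in the opposite one, where independent calls would give 505.4 and 503.2. Of the shared genes, 30.8% were called after EPZ015666. Both comparisons use the same DMSO libraries, which by themselves make changes look alike: in simulations without any effect, the correlation across genes was 0.609 on average (0.544 to 0.663), against 0.132 in the data (Spearman 0.0443). These correlations cannot be compared, since real effects add to the spread in the data but not in the simulations. No gene was called in both there by edgeR, which with so few simulated calls says nothing on the overlap. The covariance was 0.0921 against 0.0681 (0.0581 to 0.0792) simulated. The 9 libraries numbered 37 to 51 gave 562 and 495 genes, and the fit without the 3 libraries that stand apart 412 and 396. The count in the same direction was 357 without DMSO replicate 2. The opposite count was 340 without DMSO replicate 2, 341 without DMSO replicate 3, 363 without EPZ015666 replicate 1 and 343 with limma on log2 TPM.

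**Figure D4:**
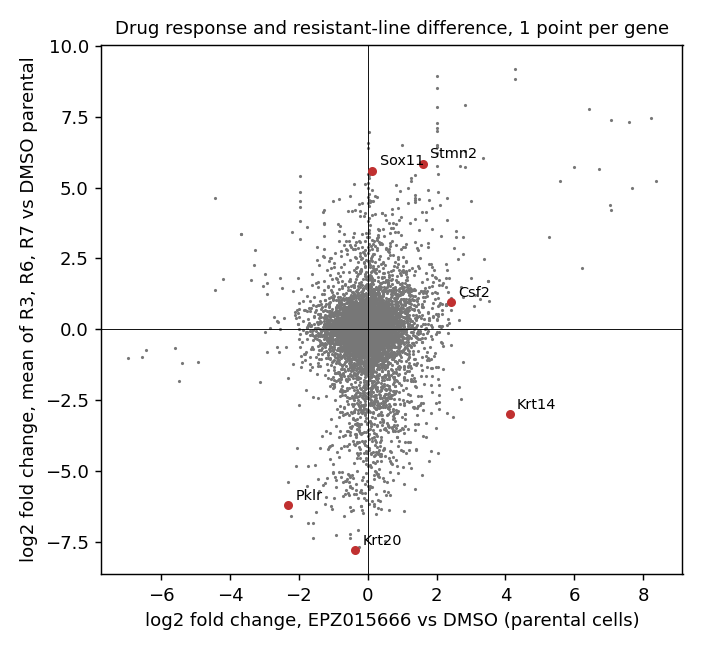
Log2 fold change of each tested gene after EPZ015666 in parental cells (horizontal) against its log2 fold change in the mean of the resistant lines (vertical), both against DMSO-treated parental cells. The correlation across genes is 0.132, and Stmn2 is marked.

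Resistant lines were last set against EPZ015666-treated parental cells, in which 8306 genes differed (4110 higher in the lines, 4196 lower). The 9 libraries numbered 37 to 51 gave 8386 and the fit without the 3 libraries that stand apart 7934. Mef2c, a transcription factor of muscle and neurons, was 122-fold higher in the lines (21.7 to 4820), Blk 174-fold (31.1 to 6880), Ptchd4 171-fold (30.6 to 6760) and Cldn34c1 at least 58.9-fold, and Mtus2 rose by 5.54 (6.24 without EPZ015666 replicate 3). The keratin gene Krt23 had 0 counts in R3 and R7 (at least 104-fold and 130-fold lower). Its fitted mean over the lines, -7.98 (-9.04 without R6 replicate 1), rests on those 0 counts, so the data do not set its size. Anxa10 was at 89.1 ± 3.23 CPM in treated cells and 1.06 ± 2.46 in the lines (-7.48, and -8.58 without R6 replicate 1), Krt20 at -7.43 (-8.92 without it), Hnf1a at -7.42 (-8.85 without it) and Krt14 at -7.11 (-7.75 without R3 replicate 1). The largest one-library moves of the rises were to 8.96 for Ptchd4 without EPZ015666 replicate 1, and to 8.95 for Blk and 8.53 for Mef2c without EPZ015666 replicate 3. Each leaves the treated group with 0 counts of the gene, so these are fitted values whose size the data do not set. The same holds for the means of Hnf1a, with 0 counts in R3, and of Krt14, with 0 counts in R7.

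In all, 8 lists differed between lines and treated cells. ATF4 genes were lower in 15 of 17 with none higher (Trib3 3.62 against 40.7 CPM, -3.50, and the glutathione-degrading Chac1 -2.43), epithelial genes lower in 16 of 18, nucleolar genes lower in 15 of 20 (Odc1 -1.54, Ncl -0.92), and MHC class I genes higher in 6 of 7 (Tapbp 1.92, H2-T23 1.31, both on chromosome 17). Gastrointestinal genes had 3 higher and 6 lower of 10, ABC transporters 3 and 6 of 11, YAP/TAZ targets 5 and 7 of 13 (Nt5e -5.95, and -6.57 without R3 replicate 3, Amotl2 -1.24, Dlc1 0.94), and DNA repair genes 12 and 3 of 20 (13 and 3 adjusted over the list alone; Rad51c 1.07 on chromosome 11 and Msh2 1.00 on chromosome 17). Camera gave adjusted p of 1.9e-14, 5.3e-07, 0.00144, 0.00836, 0.0243 and, for the last 3 lists, 0.0329. None passed with an estimated correlation in limma's camera, where adjusted p = 0.17 for ATF4 and MHC class I genes, 0.24 for epithelial, 0.45 for gastrointestinal, ABC and DNA repair, 0.61 for YAP/TAZ and 0.74 for nucleolar genes. The series term gave 0.074 for gastrointestinal, DNA repair and YAP/TAZ genes and 0.0631 for ABC transporters, ending these calls. The replicate block gave 0.0655 for ABC transporters and 0.0747 for YAP/TAZ targets, and without the 3 libraries that stand apart ABC (0.0692), DNA repair (0.075) and YAP/TAZ genes (0.135) no longer passed.

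Gene position also parted the lines from parental cells. Over genes with a mean of at least 5 CPM, the median log2 fold change against DMSO, relative to the genome median, was 0.318 in R3, 0.287 in R6 and 0.257 in R7 on chromosome 11, 0.346, 0.327 and 0.357 on chromosome 17, and 0.281, 0.275 and 0.222 on chromosome 18. EPZ015666 gave 0.006, 0.002 and 0.034 on these. Chromosome 8 lay lower in each line (-0.16, -0.256 and -0.166), and also after EPZ015666 (-0.103), and chromosome 10 stood apart in R6 (0.229), with 0.109 in R7 and -0.034 in R3. Chromosome 13 also stood higher in each line (0.205, 0.142 and 0.129 in R3, R6 and R7). Chromosome 14 was split: over its first 20 Mb the medians were -0.358, -0.318 and -0.278, from 20 to 40 Mb -0.278, -0.224 and -0.186, and from 60 to 80 Mb 0.315, 0.353 and 0.384. Chromosome 3, which carries Stmn2, lay lower (-0.133, -0.088 and -0.152) as a median, and Trp53 and Krt20 lie on chromosome 11.

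**Figure D5:**
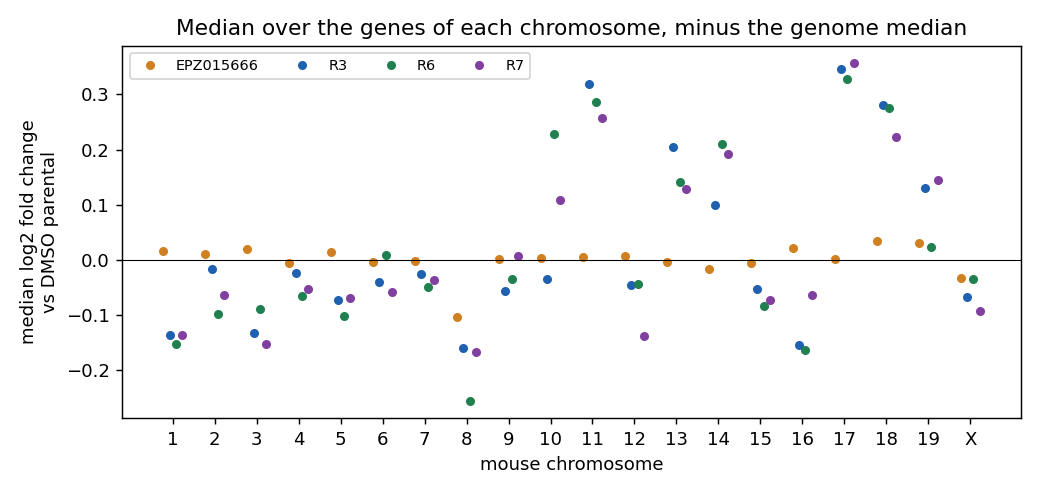
Median log2 fold change against DMSO-treated parental cells over the genes of each mouse chromosome, minus the genome median, for EPZ015666 and for R3, R6 and R7. Chromosomes 11, 17 and 18 sit between 0.222 and 0.357 in the 3 lines and at most at 0.034 after EPZ015666.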

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

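The tests of drift, of parental-like cells, of resistant-type RNA, of outgrowth, of gene dosage and of a shared ancestor were chosen only after the result was seen, and the others before. Differences between resistant lines were picked out because the effect of 1 line against DMSO-treated parental cells differed from that of another by a test of the difference itself. R3 and R6 differed in 4247 genes, R6 and R7 in 2717, and R3 and R7 in 416. Stmn2 was higher in R3 than in R6 by 0.608 on the log2 scale. Among all genes 186 were called in opposite directions in 2 of the lines, for which no separate explanation was tested.

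R6 replicate 1 held parental-type transcripts that the other R6 libraries nearly lacked. The 11 markers were chosen without R6, and to be low in the R3 and R7 libraries (0.204% to 1.37%). R6 replicate 1 held them at a median of 14.7% of the parental level, against 2.16% and 1.59% in replicates 2 and 3. If parental RNA or cells had entered the library, genes high in R6 and near 0 in parental cells should be diluted, and 7 such genes stood at a median ratio of 0.862 to the other replicates (85.7% of them below 1), while 2043 genes that do not differ stood at 0.992. Gene-by-gene drift toward the parental state cannot be told apart from it, since the spread of the parental share over 49 markers, 0.368, lay between the median (0.318) and the highest (0.464) of 200 simulated mixtures, and a simulated bound excludes nothing. Parental-like cells living in the R6 culture would give the same share, 15.3% (10.8% to 20.5% over the central markers), so they stay open as well. The dilution is consistent with about that share of parental material, as a hypothesis found and tested on the same library.

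DMSO replicate 3 and EPZ015666 replicate 3 held slightly more of 23 resistant-type transcripts, at medians of 4.27% and 4.61% of the resistant level against 2.08% and 2.78%, and 2.42% and 3.07%, in their sister libraries. The share of markers above the mean of the 2 sister libraries was 73.9% and 82.6%, which a small amount of resistant-line RNA or cells could give, but the markers were picked from these libraries and cannot decide. Outgrowth of resistant cells under the inhibitor cannot be told apart from it in the treated library: the gap was 1.433 points in the library kept in DMSO and 1.848 with EPZ015666, but both rest on the same markers and on 1 library of each group. An effect common to libraries numbered 53 to 57 cannot be told apart from a mixture, because R3 replicate 2 and R6 replicate 3 of that series had 73.9% and 56.5% of the markers above their sisters. The same libraries carry the highest Stmn2 of their groups (4.48 and 12.6 CPM).

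Chromosomes 11, 17 and 18 stood higher in all 3 lines. A few strongly changed genes hardly move a median over 271 to 872 genes. That the chromosome medians without genes changed 2-fold kept at least 0.875 of their size was thus nearly set in advance. It is no separate evidence. All 9 resistant libraries lay above each EPZ015666 library on these chromosomes (lowest 0.184, highest treated library 0.045). They come from every series of library numbers, so an effect of a single library or series is argued against. The chromosomes were picked from these same libraries, which made this outcome likely. A difference in culture or handling between parental and resistant cells goes with the groups and cannot be told apart. A difference in gene dosage over whole chromosomes is a candidate explanation: all 17 bins of 20 Mb lay above the genome median in each line, the lowest at 0.096, against 11 of them after EPZ015666. A single ancestor of the lines could also be read from bin medians that went together (r = 0.846 for R3 and R6 across 137 bins, 0.926 for R3 and R7, against 0.162 for R3 and EPZ015666, which share the same DMSO libraries), but independent selection of the same dosage would give the same, so it cannot be told apart. No DNA was measured, and a gain in the lines and a loss in the parental culture would look alike.

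Other splits of the same libraries were fitted for each count. For the comparisons of 3 against 3 libraries there are only 10 splits, too few for a share under 0.05: only 1 of 10, the real one, gave as many genes for EPZ015666 (3663, highest other 0), R3 (5732, highest other 0), R6 (6790, highest other 0), R7 (5494, highest other 0), R3 against R6 (4247, highest other 1), R3 against R7 (416, highest other 0) and R6 against R7 (2717, highest other 1). For the mean of the lines, 1 of 100 splits gave as many as the real 6788 (highest other 2177). For the lines against EPZ015666 it was 1 of 100 (8306, highest other 1617), and for the shared genes 1 of 100 (3651, highest other 443). No other split drawn reached these counts. But the other splits mix parental and resistant libraries, which raises the spread within groups, and the replicates may be technical. They therefore do not exclude chance between cultures. For the overlap in the same direction 1 of 100 gave as many (570, highest other 1), but the other splits called at most 1 shared gene and could not reach it, so they say nothing on whether the overlap exceeds that of independent calls (505.4). The number of gene lists was often reached by other splits: 43 of 100 gave at least 9 lists for the mean of the lines (highest other 16). Against EPZ015666, 40 of 100 gave at least 8 (highest other 14). Splits that mix parental and resistant libraries unequally keep part of the real difference, so they do not show what chance alone gives. The number of lists is thus not shown to exceed chance, nor to equal it. With 10 splits, again too few, 7 gave at least the real 6 lists after EPZ015666 (highest other 10), 1 the 13 in R3 (highest other 12), 6 the 8 in R6 (highest other 12) and 3 the 7 in R7 (highest other 11).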

How the results depend on the processing

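The series of library numbers, the 9-library fit, the fit without the 3 libraries that stand apart and the removal of chromosome medians were chosen only after the data were seen. Over 440 gene values and 9124 alternative values of them, 8724 kept their side of the threshold, 380 kept direction but no longer passed, 16 passed only under the alternative and 4 called values reversed, while 12 gave no value. In all 40 changed sign, the others past the threshold in neither fit. Losses came mostly from leaving out 1 library (207), limma on log2 TPM (47), the fit without the 3 libraries (38), and chromosome medians and the 9 libraries (22 each). The 207 are pooled over many refits, in which 4086 values kept their side of the threshold. As single fits, limma kept 392 and the fit without the 3 libraries 401, so each lost a larger share. Of 264 alternative counts 242 stayed within 1.5 times. With chromosome medians removed, Hnrnph1 (0.26) became -0.043, Bak1 (0.34) -0.01 and Abca3 (0.35) -0.002 in the mean of the lines, where genes lying on shifted chromosomes lose that shift by construction. With limma, Edem1 (0.33) became -0.16, and the cause was not tested.

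Counts that moved were these. R3 against R7 (416) gave 929 without the filter on low counts, 1328 with the series term, 234 in the 9 libraries and 159 to 420 leaving out 1 library of the groups compared (366 to 522 for 1 of the other groups). R6 against R7 (2717) gave 1688 with limma and 1711 to 2662 leaving out 1 library of these groups (2427 to 2940 for the others). The overlap with EPZ015666 gave 357 to 601 genes in the same direction (570) leaving out 1 library, and in the opposite direction (555) 340 to 586, and 343 with limma. With an estimated correlation, camera kept 0 lists for EPZ015666, 0 for R3, 1 for R6, 0 for R7, 0 for the mean of the lines and 0 for the lines against EPZ015666, where the series term kept 4 and the fit without the 3 libraries 5. The cause was not tested for any of them, except that the 9 libraries and the left-out libraries mean fewer samples. Leaving out 1 library of the groups compared gave 2474 to 3711 genes for EPZ015666, 4926 to 5399 for R3, 5902 to 6631 for R6, 4705 to 4930 for R7 (for 1 of the other groups 3463 to 3913, 5614 to 6016, 6674 to 6972 and 5426 to 5802) and 3064 to 3648 shared genes. The other alternatives gave 2776 to 4773, 4583 to 6260, 5833 to 7640, 4541 to 6127 and 2923 to 4103.

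Stmn2 kept its call in every alternative run for EPZ015666 (1.07 to 2.35 leaving out 1 library of the groups compared, 0.90 with limma), R3 (up to 7.03), R6 (5.41 to 6.43) and R7 (5.32 to 6.34). Its difference between R3 and R6 no longer passed with DESeq2 (0.608, adjusted p = 0.178) or limma (0.528, 0.211), and was 0.524 to 0.64 leaving out 1 library. R3 against R7, 0.70 and just short of the threshold, passed without the filter (0.682), with only the libraries compared (0.697), with the replicate block (0.697), with the series term (0.622), in the 9 libraries (0.58) and without the 3 libraries (0.689). The cause was not tested.

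Over all groups, replicate numbers paired libraries weakly at most. After group means were removed, 30 same-number pairs correlated at 0.039 on average (-0.124 to 0.238), against -0.019 for other numbers. In all, 8 of 15 libraries went best with their own number. Among the treated libraries, each DMSO library went best with that of its own number (0.15, 0.029 and 0.238), so a pairing there is not excluded. The labels do not state one. With the replicate block anyway, edgeR called 3808 genes for EPZ015666, 5791 for R3, 6867 for R6, 5633 for R7, 6878 for the mean of the lines, 8359 for the lines against EPZ015666, 4338, 441 and 2824 between lines (R3 and R6, R3 and R7, R6 and R7), 3723 shared genes, and 592 and 597 in the overlap. Libraries numbered 53 to 57 went together more (0.178 on average) than those of different series (-0.049). Splitting the DMSO libraries between comparisons was not run, since 1 part would hold a single library, so part of the overlap may come from the shared libraries, and the covariance beyond the simulated one (0.024) is given instead. Small changes were often missed in simulated data with few changed genes: for EPZ015666, 50% of simulated 1.5-fold changes were recovered. The parts of depth, spread and number of libraries were not tested apart. With the many more genes called in the data the adjusted threshold is less strict, so that share need not hold there.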

Other observations

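The values given here come from tests fixed before the data were examined, and none was chosen only after its result was seen. In the mean of the resistant lines 51.2% of all 13259 tested genes were called, 3328 higher and 3460 lower. List counts near that share, in mixed directions, say nothing on a list. The lists that follow did not pass camera as a group. Of 10 imprinted genes 6 rose and 4 fell (adjusted p = 0.381), with Snrpn, a small ribonucleoprotein gene of that class, from 0.963 ± 0.512 to 16.9 CPM (4.09), and Ndn, the growth suppressor necdin, lower (-2.43). Of 18 collagen and matrix genes 8 rose and 4 fell (0.414), with Col6a1 from 13.9 ± 3.37 to 104 CPM (2.85), and of 16 mesenchymal genes 8 rose and 3 fell (0.362), with Fbn1, the microfibril protein fibrillin, at 3.54, Twist2 at 2.97, smooth muscle actin Acta2 at -2.92 and Loxl2 at -1.28. Of 17 NF-kB targets and cytokines 9 rose and 4 fell (0.414), with the granulocyte factor Csf3 (3.02) higher and the chemokine Cxcl5 lower (-2.92). Of 12 Wnt and Notch targets 5 rose and 3 fell (0.689), with the Wnt inhibitor Notum from 0.177 CPM to 4.88 in R3, 9.46 in R6 and 4.91 in R7, Axin2 at 1.06, Dkk1 at -3.79 (-4.43 without R3 replicate 2) and Hey1 at -2.09.

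Microtubule genes also differed in the lines, although neither list passed: of 22 stathmin family and microtubule regulators, Stmn2 included, 9 rose and 7 fell (0.286), with the microtubule-binding kinase Dclk1 from 7.57 ± 2.06 to 132 ± 47.1 CPM (4.07) and Map1b lower (-1.14), and of 13 tubulins 7 rose and 2 fell (0.414), with Tubb2b at 1.03 and Tubb4b at -0.38. Of 9 neuronal genes 4 rose and 2 fell (0.689), with Eno2 at 1.65 and Prph at -2.59. For the other lists in the lines, rises and falls were 2 and 3 of 17 arginine methyltransferase genes (0.745; Mat2b 0.79, Prmt7 -0.39), 3 and 3 of 20 Sm and snRNP genes (0.665; median -0.03, mean 0.15), 3 and 3 of 23 SR and hnRNP genes (0.689; 3 and 1 adjusted over the list alone), 5 and 4 of 27 G1/S genes (0.689), 8 and 5 of 24 G2/M genes (0.745; 8 and 6 adjusted over the list alone; median -0.04, mean 0.02), 8 and 2 of 20 DNA repair genes (0.286; 8 and 3 adjusted over the list alone), 6 and 7 of 19 p53 targets (0.745; median 0.00, mean -0.23), 2 and 1 of 8 CDK inhibitors (0.897; median 0.07, mean -0.31) and 2 and 2 of 13 BCL2 family genes (0.689). They were 9 and 8 of 22 RAS/MAPK output genes (0.703; Areg 1.20; median -0.08, mean 0.22), 3 and 6 of 13 YAP/TAZ targets (0.185; Nt5e 161-fold lower in R3, 28.5 to 6420), 5 and 3 of 13 TGF-beta and BMP targets (0.897; Serpine1 -1.12), 2 and 4 of 8 lung lineage genes (0.665; Cldn18 -2.83, Foxa2 -1.44), 4 and 4 of 16 unfolded protein response genes (0.745; 4 and 6 adjusted over the list alone), 3 and 9 of 16 hypoxia and glycolysis genes (0.11; Pfkfb3 -1.29, Pdk1 -1.22), 4 and 6 of 36 ribosomal protein genes (0.745; 3 and 3 adjusted over the list alone), 7 and 0 of 13 mitochondrially encoded genes (0.362; mt-Nd5 0.81), 0 and 0 of 2 leukocyte markers (0.745) and 1 and 0 of 2 endothelial markers (0.655; 2 and 0 adjusted over the list alone).

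After EPZ015666 in parental cells, where 27.6% of all tested genes were called, the remaining lists did not pass camera either. Rises and falls were 5 and 1 of 16 mesenchymal genes (0.105), with the transcription factor Prrx1 at 1.65, 3 and 0 of 13 TGF-beta targets (0.131; Tgfb2 1.02, Serpine1 0.78), 4 and 2 of 13 YAP/TAZ targets (0.153; 5 and 3 adjusted over the list alone; Amotl2 0.77), 6 and 2 of 22 RAS/MAPK genes (0.0642; 8 and 2 adjusted over the list alone; the phosphatase gene Dusp5 0.83) and 3 and 2 of 17 NF-kB genes (0.328; Mmp3 2.11). They were 3 and 0 of 13 interferon-stimulated genes (0.545; 2 and 0 adjusted over the list alone), 1 and 2 of 7 MHC class I genes (0.625; median 0.05, mean -0.15; Tapbp -0.63), 2 and 1 of 18 epithelial genes (0.657; median -0.02, mean 0.03), 3 and 1 of 18 collagen genes (0.582), 0 and 2 of 8 lung genes (0.583), 1 and 0 of 10 gastrointestinal genes (0.472), 0 and 2 of 11 ABC transporters (0.296), 5 and 1 of 16 unfolded protein response genes (0.582; median -0.04, mean 0.05), 3 and 5 of 16 hypoxia genes (0.472; 4 and 5 adjusted over the list alone), 2 and 1 of 12 Wnt and Notch targets (0.472; 2 and 0 adjusted over the list alone), 2 and 1 of 36 ribosomal protein genes (0.223; 1 and 1 adjusted over the list alone), 2 and 0 of 10 imprinted genes (0.328), 0 and 0 of 13 mitochondrial genes (0.328), 0 and 1 of 2 leukocyte markers (0.627) and 1 and 0 of 2 endothelial markers (0.392; Kdr 1.46).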
